A study of Schizophyllum commune with 6 samples.

How the data were processed

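The samples were mycelia of Schizophyllum commune from 3 groups, wild type 12-43, wild type E6 and a knockout of dhc2, with 2 libraries each. Per the labels' protocols, mycelium was grown on solid CYM medium at 28 °C, moved onto cellophane and grown for 3 days, total RNA was taken with a plant RNA kit, and an mRNA-based cDNA library was sequenced as single reads of 50 bases. The quality reports deposited with the values give a read length of 51 and totals of 17735309 to 25842890 reads per library.

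The authors deposited RPKM (reads scaled by model length and by library depth) for 14652 gene models, per the file headers, followed by a FastQC 0.9.2 report of the raw reads. The submitters' processing notes name TopHat, DESeq and edgeR, with no role or version. The aligner settings, the counting rules, the use of strand, the genome build and the annotation are not given in the sources used here. Reads that fit several near-identical genes, or overlapping and antisense genes, can therefore be split in unknown ways.

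RPKM are not counts. The low values were whole multiples of a step, so that the reads, the denominator N of each library and the length of each model could be solved for, RPKM being in proportion to reads over N and length. Of 13715 models with a value above 0 in any library, 13715 (100%) came out whole to within 0.005 reads plus rounding of the printed digits, and 937 models were at 0 in all libraries. Of 500 sets of values scrambled between models 0 came out whole. These sets were drawn only from models with reads in all 6 libraries, of which there were 12480. A model read in few libraries can meet some length by accident, so its coming out whole decides little. Lengths were taken as multiples of 3, as 99.1% were when this was not required, so they are coding lengths. N was 14054525 and 8769918 for 12-43 replicates 1 and 2, 14372979 and 13857189 for the knockout, and 9210239 and 13012283 for E6, which is 46.0% to 58.7% of the raw reads. The recovered reads summed to 98.5% to 99.8% of N. They are the smallest whole numbers that fit and are lower bounds where the reads of a model share a factor, while ratios between libraries are not affected. On simulated data (14652 models) N was exact in 6 of 6 libraries. Among the simulated models with reads in all 6 libraries the reads were exact in 99.2%, and 0.784% came out below and 0% above the truth. Models without a read in some library were not scored. A value of 0 allows up to 3 reads, which is 0.209 to 0.342 RPKM for a model of 1 kb. Intervals and floors cover counting error only, as does the number of models expected at 0 in 12-43 from depth alone, which was summed over models from the chance of 0 reads given the knockout reads (gamma-Poisson).

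The fit planned before the data were examined, edgeR's quasi-likelihood test on counts, was not used, because the files hold RPKM. The main test was limma 3.58.1 (R 4.3.3) on log2(RPKM + 0.5) with trended moderated variance, all 6 libraries in 1 fit with 3 residual degrees of freedom and group as the term, and Benjamini-Hochberg adjustment over all tested models with a threshold of 0.05. Each adjusted p of a gene is from this test. RPKM were scaled between libraries by trimmed means of M values (30% of M and 5% of A trimmed), with factors of 0.954 to 1.05. Models entered if at least 2 libraries had 0.744 CPM relative to N (10 reads at the median depth) and all libraries together 15 reads, which kept 12484. Fold changes on this scale understate the change of low genes. Genes with no read in a group have a fold only as a bound, against 3 reads in each library of that group, and those with 1 to 3 reads a ratio of reads per read of N with an exact binomial interval. On simulated data of 12484 models with 200 changed, 84% of 2-fold and 100% of 4-fold changes were recovered for the knockout against 12-43, with 4.17% false among the calls. For E6 against 12-43 these were 86%, 99% and 6.57%, and for the knockout against E6 80%, 100% and 5.76%. In these simulations few models changed, evenly up and down, and the groups had the same spread. In the data 54.6% to 62.7% of models were called. The SD of log2 ratios between replicates was 0.259 in 12-43, 0.104 in the knockout and 0.193 in E6. The simulated shares therefore need not hold for the data.

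Replicates differed by more than counting noise, with a mean chi-square per model of 38.6 for 12-43, 3.17 for the knockout and 20.9 for E6, so no libraries were merged as duplicates. The library group used as a covariate was read from the lists of enriched 5-base sequences in the quality reports. GC content was 59% in the 3 libraries with GAAGA listed and 57%, 56% and 58% in 12-43 replicate 2 and E6 replicates 1 and 2.

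Identifiers were matched to the RefSeq gene table of assembly Schco3 (strain H4-8) by current or older locus tag, for names and neighbours only. Of 14652 identifiers 3634 matched, 2018 by the current tag and 1616 by the older tag, and 4 were ambiguous and left out. The coding length lay within the matched gene's span for 99.1% of matches, against 66.2% when shuffled. A gene symbol was found for 39 identifiers. The table has no product text, so that of the 31 gene lists fixed before the data were examined only the transcription factor list met any symbol, and that 1, too few for a test. In their place hydrophobins, B mating-type genes and fruiting-body regulators were listed by symbol after the data had been examined, and tested with limma's camera at a correlation of 0.01 if at least 5 members were tested, with an estimated correlation and with fry as alternatives. Camera ran on the log2 RPKM and not on voom values as planned. Hyd3, Hyd7 and Hyd8 did not pass the read filter, and bap3-1 had no read.

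Named genes followed a rule fixed before the data were examined. With no product text it allows, per comparison, the 2 largest rises and 2 largest falls without a symbol among called models whose groups did not overlap and had at least 10 CPM relative to N in the higher group. Genes with a symbol were added after the data had been examined. The gene dhc2 was not matched and is not reported. Overlaps between comparisons that share libraries were set against 20 simulations of unchanged groups. Alternatives covered scaling, read filters, limma voom on the recovered reads, a fit of the compared groups alone, the replicate number as a block, and leaving out each library. Added after the data had been examined were pseudocounts of 0.1 and 2, unscaled RPKM and the library group as a covariate. Recovery of reads used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.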

Results

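Gene expression was measured by RNA sequencing in mycelium of the split-gill mushroom Schizophyllum commune, a basidiomycete whose mating is governed by the A locus, which encodes homeodomain proteins, and the B locus, which encodes lipopeptide pheromones and their receptors. There were 6 libraries in 3 groups of 2. Wild-type strain 12-43 carried mating type A3,5 with B2,2, wild-type strain E6 carried A4,6 with B2,1, and a strain lacking dhc2, which the labels name as a dynein heavy chain gene, carried A3,5 with B2,2 as 12-43 did. Dynein is a motor that carries cargo along microtubules. The strain labels call the samples monokaryons, that is, mycelia with 1 type of nucleus, whereas the growth protocol describes mycelium taken from a mating interaction and grown for 3 days at 28 °C, and nothing in the labels settles which description applies. The deposited RPKM covered 14652 gene models. The reads behind them, recovered from the values, were expressed against denominators of 14054525 and 8769918 reads in the 12-43 libraries, 14372979 and 13857189 in the dhc2 knockout and 9210239 and 13012283 in E6. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

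The libraries grouped by strain. The first 2 principal components of the 12484 tested models held 53.2% and 42.5% of the variance and set the 3 groups apart. Across genes, which are not independent replicates, log2 values within a group correlated at 0.989 for 12-43, 0.996 for the dhc2 knockout and 0.992 for E6, against 0.855 to 0.885 between groups. The quality reports of the reads gave a further split. In 12-43 replicate 1 and in both knockout libraries the 5-base sequence GAAGA was listed as enriched, at 3.00, 3.03 and 3.07 times its expected frequency, and in 12-43 replicate 2 and both E6 libraries it was not listed. The 12-43 libraries therefore lay on different sides of this split, and each comparison below is also given with this library group as a covariate. In that fit the knockout is set against 12-43 replicate 1 and E6 against 12-43 replicate 2. Each 12-43 library is then fitted exactly, so the spread behind its p-values comes from the knockout and E6 pairs alone, although 12-43 had the largest spread between replicates.

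**Figure D1:**
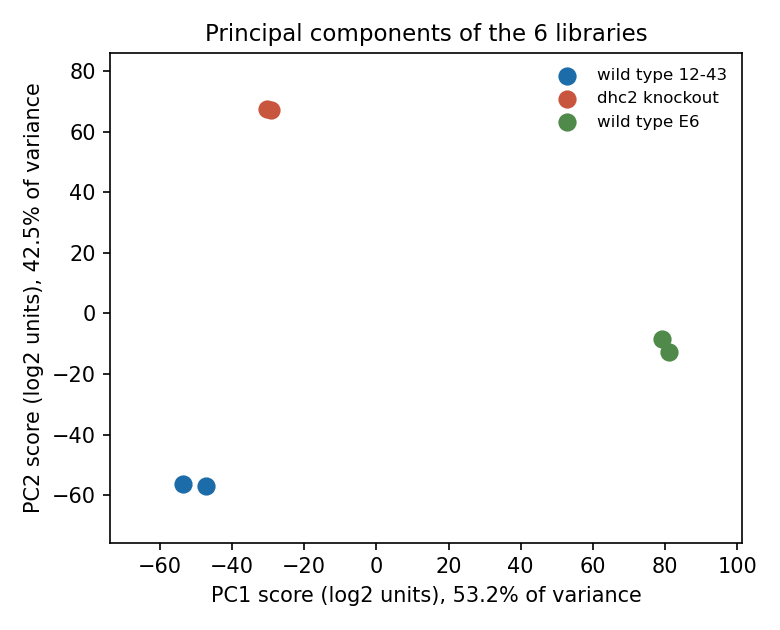
Scores of the 6 libraries on the first and second principal components (log2 units) of log2(RPKM + 0.5) over 12484 models. Each point is a library, coloured by group, and the axes hold 53.2% and 42.5% of the variance; the 2 libraries of each group lie next to each other.

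Genes named for a B specificity gave a mixed check of the strain labels. The receptor gene bbr2 belongs by its symbol to a specificity that the labels give to 12-43 and the knockout but not to E6. It had 503 and 207 reads in 12-43, 719 and 729 reads in the dhc2 knockout, and 1 and 3 reads in E6. The receptor gene bar3 and the pheromone gene bap3-3 are named for specificity 3, which the labels give to none of the groups at the B locus, yet bar3 had 311 and 166, 243 and 207, and 351 and 444 reads in 12-43, the knockout and E6, and bap3-3 had 58 and 31, 259 and 275, and 23 and 21. Whether these reads come from the named genes, from related sequences or from strains other than labelled was not tested, so the values of bar3 and bap3-3 are those of the gene models only. The identifier of dhc2 itself was not paired with a name in the tables used here, so the reads of the deleted gene are not reported and do not check the knockout label. Only 2 models, of 483 and 432 nt, had at least 50 reads in each wild-type library and at most 5 in each knockout library. Whether dhc2 had that many reads in the wild types is not known.

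The comparison of the dhc2 knockout with 12-43 asked which genes changed in the strain without the dynein gene, at the same labelled mating type. Hydrophobins, small secreted proteins that coat aerial hyphae and fruiting bodies, were lower in the knockout. Of 9 tested hydrophobin genes, 7 fell, none rose and 2 did not pass the test. SC4, known from the dikaryon and fruiting bodies, was at 380 ± 183 RPKM in 12-43 (SD, n = 2) and at 6.72 ± 1.91 RPKM in the knockout (SD, n = 2), a log2 change of -5.65 (SE 0.34, limma adjusted p = 1.42e-05). SC3, the abundant hydrophobin of aerial hyphae, fell from 12387 ± 2093 to 4773 ± 97.6 RPKM (SD, n = 2 each), a log2 change of -1.36 (SE 0.19, limma adjusted p = 0.00085). HYD2 changed by -4.91 on the log2 scale (SE 0.37, limma adjusted p = 3.56e-05) and by -4.32 without knockout replicate 1, Hyd9 changed by -3.20 (SE 0.33) and SC1 by -1.69 (SE 0.31). With the library group as a covariate SC4 changed by -5.10, SC3 by -1.15, HYD2 by -5.10, Hyd9 by -2.68 and SC1 by -1.18, and all 5 stayed past the threshold. SC6 and Hyd4 differed by 0.40 (SE 0.22) and -0.12 (SE 0.27) without passing it. The set test of the hydrophobins (camera) gave an adjusted p of 0.0041 and, with an estimated correlation, an adjusted p of 0.21, so the call on the list was lost there. With the covariate camera's adjusted p was 0.0065. The list was drawn up from gene symbols after the data had been examined.

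The B mating-type genes went the other way. Of 13 tested genes 10 rose, 1 fell and 2 did not pass the test, and adjusted over the list alone 10 rose and 2 fell. All 8 tested pheromone genes were among those that rose, though the call on bbp2-6 was lost without knockout replicate 2 (adjusted p = 0.073). The pheromone gene bap3-3 was at 19.95 ± 2.18 RPKM in 12-43 and 98.6 ± 6.72 RPKM in the knockout (SD, n = 2 each), a log2 change of 2.28 (SE 0.19, limma adjusted p = 6.72e-05). The pheromone gene bbp2-2 went from 12.3 ± 1.92 to 79.0 ± 5.04 RPKM (SD, n = 2 each; log2 change 2.64, SE 0.27, limma adjusted p = 0.00017), and bbp2-1 from 29.0 ± 1.57 to 70.3 ± 0.902 RPKM (SD, n = 2 each; log2 change 1.27, SE 0.12). The gene bbp2-5 had 0 and 1 read in 12-43 and 38 and 44 reads in the knockout, a ratio of 66.3 per read of the denominator with an exact 95% counting interval of 11.6 to 2650. The receptor bbr2 rose by 0.80 (SE 0.19, limma adjusted p = 0.011), a call that was lost without knockout replicate 1 (adjusted p = 0.055) and without knockout replicate 2 (adjusted p = 0.068). The receptor-like gene brl1 rose by 1.06 (SE 0.17) and brl3 fell by 0.44 (SE 0.087). The receptor bar3 (log2 change -0.34, SE 0.14) was not called over all models (adjusted p = 0.067), but was adjusted over the list alone (0.042), with upper-quartile scaling (0.039) and with voom (0.040). With the library group as a covariate the log2 changes were 2.21 for bap3-3, 2.53 for bbp2-2, 1.26 for bbp2-1, 4.41 for bbp2-5, 0.55 for bbr2 and 0.90 for brl1, all past the threshold. Camera gave an adjusted p of 0.0041 for the list, 0.21 with an estimated correlation and 0.0089 with the covariate. The call on the list was also lost with a mean of at least 50 reads (adjusted p = 0.23). It was lost too without models that had under 3 reads in each library of any of the 3 groups (8 genes left, adjusted p = 0.28). That filter counts E6, which is not compared here. It removed bbp2-1, bbp2-2 and the bbp2 copy 251507 only for their 0 or 1 read in E6. They had 172, 57 and 44 reads in 12-43 and 512, 442 and 168 in the knockout. This loss therefore does not come from low reads in the compared groups alone. Pheromone genes are short members of a family, and reads shared between near-identical copies make the value of any single copy uncertain.

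**Figure D2:**
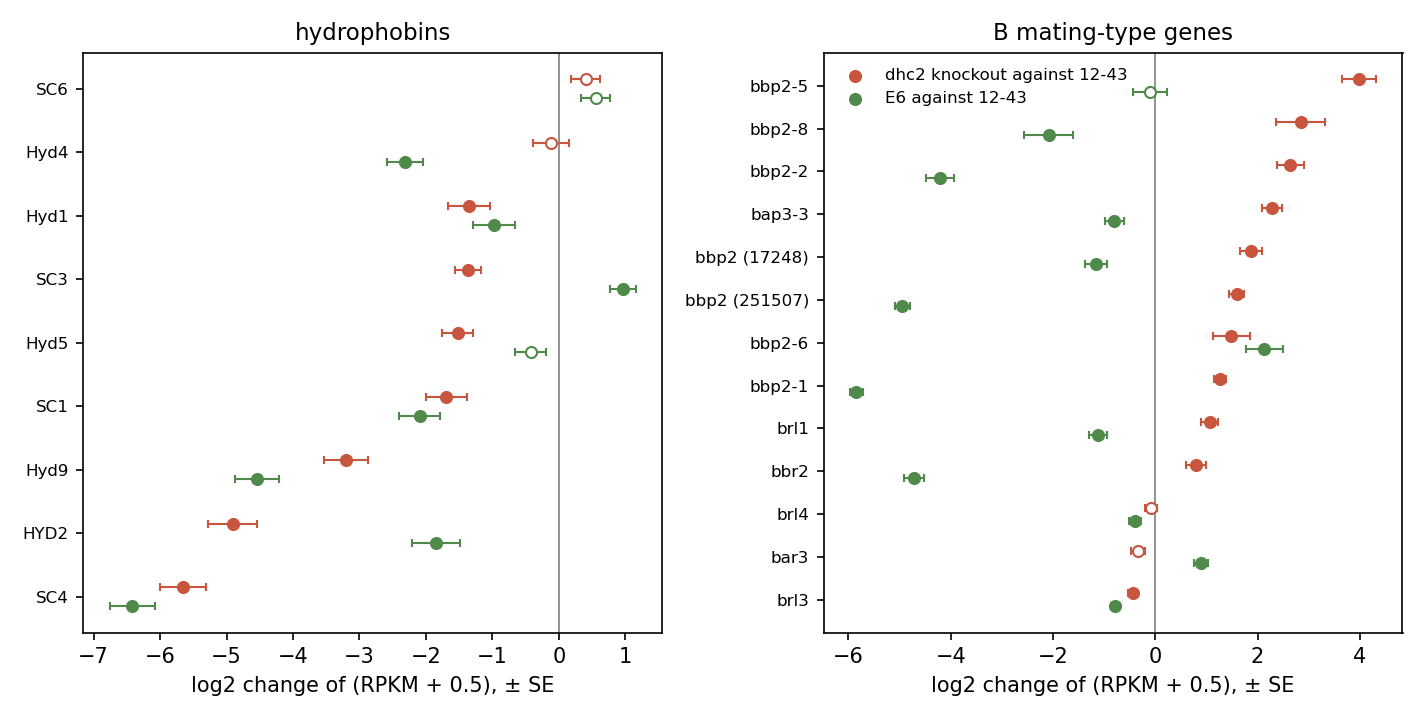
Log2 change of (RPKM + 0.5) with its SE for 9 hydrophobin genes (left) and 13 B mating-type genes (right), in the dhc2 knockout against 12-43 and in E6 against 12-43 (n = 2 libraries per group). Filled points passed the limma adjusted p of 0.05; in the knockout 7 hydrophobins lie below 0 and 10 B genes above 0 among the filled points.

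Few regulators of fruiting-body formation were called in the knockout. Of 8 tested genes, which include the blue-light receptor WC1, its partner WC2 and the transcription factors Fst3, Fst4, hom1, c2h2, Gat1 and Bri1, none rose and 1 fell (camera adjusted p = 0.94, and 0.56 with the covariate). The call depended on the setting for further genes: c2h2 (log2 change -0.30, SE 0.13) was called lower with the covariate (-0.42, adjusted p = 0.034), with upper-quartile scaling (0.042), with voom (0.048) and without 12-43 replicate 2 (0.034), and WC1 (0.29, SE 0.12) was called higher with voom (0.029). The gene called in the fit of all libraries was WC2, with a log2 change of -0.33 (SE 0.11, limma adjusted p = 0.038), a call that was lost without 12-43 replicate 1 (adjusted p = 0.14), without knockout replicate 1 (0.19) or 2 (0.12), without E6 replicate 1 (0.057) or 2 (0.057), with only the compared groups in the fit (0.050) and with unscaled RPKM (0.060). With the covariate it was kept (-0.43, adjusted p = 0.020). Among the other genes with a symbol, ura1, which encodes orotidine-5'-phosphate decarboxylase of pyrimidine synthesis and is used as a transformation marker in this species, rose the most. It was at 9.25 ± 2.14 RPKM in 12-43, 214 ± 0.913 RPKM in the knockout and 14.4 ± 0.302 RPKM in E6 (SD, n = 2 each), a log2 change of 4.48 against 12-43 (SE 0.17, limma adjusted p = 2.12e-06) and of 4.74 with the covariate. EGC1 fell by 0.71 (SE 0.10). The laccase gene Lcc1 rose by 0.69 (SE 0.17), a call lost without knockout replicate 2 (adjusted p = 0.095), and CFS2 fell by 0.73 (SE 0.18), a call lost without 12-43 replicate 2 (0.053), knockout replicate 1 (0.073) or knockout replicate 2 (0.065). The second laccase gene, Lcc2, differed by 0.12 (SE 0.25) and did not pass the test.

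Among models without a symbol, the largest rises were those of model 1291435, with 2 and 3 reads in 12-43 and 3570 and 3166 in the knockout, and model 1211065, with 5 and 3 against 3552 and 3175 reads. The largest falls were those of model 1189960, from 370 ± 36.4 to 1.70 ± 0.336 RPKM (SD, n = 2 each), and model 1100973, with 229 and 383 reads in 12-43 and 0 in each knockout library. Model 1100973 was thus at least 141-fold lower in the knockout, against a floor of 3 reads in each library, and at least 76.6-fold lower with 12-43 replicate 1 alone.

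Across all 12484 tested models, limma called 6814 between the dhc2 knockout and 12-43, 3517 higher and 3297 lower in the knockout. The balance depended on scaling, with 3202 higher and 3749 lower after upper-quartile scaling. Of the models called with the main scaling, 1682 were higher and 1096 lower by at least 2-fold. With the library group as a covariate 6264 models were called and 2785 by at least 2-fold.

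**Figure D3:**
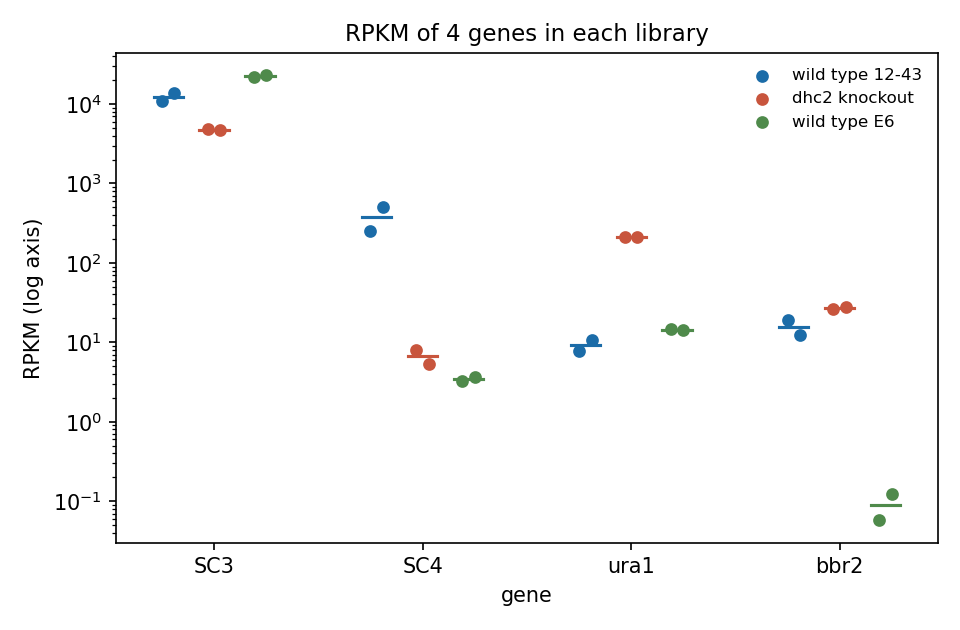
RPKM of SC3, SC4, ura1 and bbr2 in each library, on a log axis. Points are libraries and horizontal lines are means of 2; SC4 is at 380 RPKM in 12-43 and below 10 in the other groups, ura1 is at 214 RPKM in the knockout, and bbr2 is near 0.1 RPKM in E6.

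The comparison of the wild types E6 and 12-43 measured how far strains of different mating type and background differ without the knockout. The hydrophobins again differed, with 6 of 9 tested genes lower in E6, 1 higher and 2 not past the test. SC4 was at 3.45 ± 0.303 RPKM in E6 (SD, n = 2), a log2 change of -6.42 against 12-43 (SE 0.34, limma adjusted p = 6.74e-06). Hyd9 changed by -4.54 (SE 0.33), Hyd4 by -2.31 (SE 0.27) and SC1 by -2.09 (SE 0.31). HYD2 changed by -1.85 (SE 0.37), a call that was lost without E6 replicate 2 (adjusted p = 0.053). Hyd1 changed by -0.98 (SE 0.31, limma adjusted p = 0.030), a call that was lost with the covariate (0.11) and without 12-43 replicate 1 (0.11), knockout replicate 2 (0.050) or E6 replicate 2 (0.080). SC6 (0.55, SE 0.22) was called higher without 12-43 replicate 2 (0.039). SC3 was the gene that rose, to 22410 ± 846 RPKM in E6 (SD, n = 2; log2 change 0.96, SE 0.19, limma adjusted p = 0.0040). With the library group as a covariate the changes were -6.97 for SC4, -5.06 for Hyd9, -2.39 for Hyd4, -2.61 for SC1 and 0.75 for SC3. Camera gave an adjusted p of 0.049 for the list, 0.022 with the covariate and 0.38 with an estimated correlation, and the call was lost without any 1 of the 6 libraries (adjusted p from 0.096 to 0.13). It was also lost with median-ratio or upper-quartile scaling (0.051 each), without scaling (0.065), with voom (0.070), with a pseudocount of 0.1 (0.061), without the read filter (0.25) and without models that had under 3 reads in a group (0.088).

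Of the 13 tested B mating-type genes, 8 (7 bbp2 genes and bbr2) belong by their symbols to the B specificity that the labels do not give to E6. How far the result of the list in E6 comes from this labelled difference and how far from expression was not tested. Of the 13 genes 10 fell, 2 rose and 1 did not pass the test (camera adjusted p = 0.0031; adjusted p = 0.19 with an estimated correlation; adjusted p = 0.0022 with the covariate). Without models that had under 3 reads in a group, 8 of these genes were tested and camera's adjusted p was 0.088. The pheromone gene bbp2-1 had 109 and 63 reads in 12-43 and 0 in each E6 library, at least 26.9-fold lower in E6 against a floor of 3 reads in each library. The copy of bbp2 with identifier 251507 had 27 and 17 reads in 12-43 and 0 in E6, at least 6.94-fold lower. The gene bbp2-2 had 57 reads in the 12-43 libraries together and 1 in E6, a ratio of 55.5 with an exact 95% counting interval of 9.57 to 2230. Of the other 5 genes, the receptor-like genes brl1, brl3 and brl4 and the pheromone gene bap3-3 fell and bar3 rose, the last 2 being named for a specificity that the labels give to none of the groups. The genes that rose were bar3 (log2 change 0.89, SE 0.14, limma adjusted p = 0.0012) and bbp2-6 (2.13, SE 0.36, limma adjusted p = 0.0018), the latter from 3 reads in each 12-43 library to 10 and 28 in E6. The call on brl4 (log2 change -0.40, SE 0.12) was lost with the covariate (adjusted p = 0.082) and without 12-43 replicate 1 (0.084), E6 replicate 1 (0.075) or E6 replicate 2 (0.064). Sequence differences between the strains and the reference models were not analysed here, so lower reads of a gene in E6 do not separate lower expression from diverged sequence.

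Of the 8 fruiting-body regulators, 4 fell and 1 rose in E6, and the list did not pass camera (adjusted p = 0.091, and 0.16 with the covariate). It passed fry in the downward direction (fry adjusted p = 0.024). Fst3 changed by -0.87 (SE 0.12, limma adjusted p = 0.00073), WC1 by -0.60 (SE 0.12), c2h2 by -0.57 (SE 0.13) and Fst4 by -0.48 (SE 0.093). The gene that rose was WC2 (0.30, SE 0.11, limma adjusted p = 0.0496), a call that was lost without 12-43 replicate 2 (adjusted p = 0.23), without knockout replicate 1 (0.097) or 2 (0.097), without E6 replicate 1 (0.14) or 2 (0.15), with median-ratio (0.056) or upper-quartile scaling (0.058), without scaling (0.21), with voom (0.054), without the read filter (0.054) and with only the compared groups in the fit (0.093). The gene hom1 (-0.24, SE 0.14) was called lower without 12-43 replicate 2 (0.047). The laccase gene Lcc1 rose by 2.90 (SE 0.17, limma adjusted p = 1.05e-05), from 0.431 ± 0.0119 to 6.08 ± 0.453 RPKM (SD, n = 2 each), a fitted change that was 3.63 with a pseudocount of 0.1, 1.79 with a pseudocount of 2 and 3.85 with voom, and EGC1 fell by 1.42 (SE 0.10). The gene ura1 rose by 0.73 (SE 0.17), a call lost without E6 replicate 1 (adjusted p = 0.068) or 2 (0.057).

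The largest rises in E6 among models without a symbol were those of model 1190086, from 0.292 ± 0.239 to 509 ± 74.8 RPKM (SD, n = 2 each), and model 1211065, which was also among the largest rises in the knockout and was at 161 ± 4.43 RPKM in E6. The largest falls were those of model 1098759, with 1408 and 884 reads in 12-43 and 1 in each E6 library, and model 1081190, with 2604 and 1485 reads against 1 and 3. Of 12484 tested models limma called 7405 between E6 and 12-43, 3870 higher and 3535 lower in E6, of which 1820 and 1286 changed by at least 2-fold. With unscaled RPKM the balance was turned, with 3396 higher and 4016 lower. With the library group as a covariate 6591 were called and 3071 by at least 2-fold.

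The dhc2 knockout and E6 were compared to set the mutant against a second wild type. Most of the B mating-type list, 8 of 13 genes, again belongs to the specificity that the labels give to the knockout and not to E6, and how far the result of the list comes from that was not tested. In it 11 genes were higher and 1 was lower in the knockout (camera adjusted p = 0.00016; adjusted p = 0.12 with an estimated correlation and 0.11 without models that had under 3 reads in a group, where the call was lost; adjusted p = 9.0e-05 with the covariate). Outside that specificity bap3-3 (log2 change 3.08, SE 0.19, limma adjusted p = 1.65e-05) and brl1 (2.18, SE 0.17) were higher in the knockout, at 2.95 and 1.85 with the covariate, and bar3 was lower. The calls on brl3 (0.34, SE 0.087) and brl4 (0.31, SE 0.12) were lost with the covariate (adjusted p = 0.28 and 0.81) and without either knockout replicate (0.068 and 0.081 for brl3, 0.20 and 0.14 for brl4), and that on brl4 also without either E6 replicate (0.13 and 0.11), with upper-quartile scaling (0.10) and without the read filter (0.051). Within it bbp2-6 was not called (-0.65, SE 0.36). The pheromone gene bbp2-1, with 263 and 249 reads in the knockout and 0 in E6, was at least 65.2-fold higher in the knockout against a floor of 3 reads in each library, and the receptor bbr2 was at 27.2 ± 0.967 against 0.0897 ± 0.0456 RPKM (SD, n = 2 each; log2 change 5.01 with the covariate).

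Of the hydrophobins 2 were higher and 3 lower in the knockout than in E6 (camera adjusted p = 0.67, and 0.60 in the upward direction with the covariate), among them SC3 with a log2 change of -2.33 (SE 0.19, limma adjusted p = 5.87e-05) and HYD2 with -3.06 (SE 0.37). With the covariate SC3 changed by -1.90 and HYD2 by -3.45, and without knockout replicate 1 HYD2 changed by -2.48. The third gene that was lower was Hyd5 (-1.10, SE 0.23), a call lost with the covariate (adjusted p = 0.21) and without E6 replicate 1 (0.063). Hyd4 (2.18, SE 0.27; 2.35 with the covariate) and Hyd9 (1.33, SE 0.33; 2.38 with the covariate) were higher, and the call on Hyd9 was lost with voom (0.090), with a pseudocount of 2 (0.060) and without knockout replicate 1 (0.062), E6 replicate 1 (0.055) or E6 replicate 2 (0.085). SC4, low in both groups, differed by 0.76 (SE 0.34) and did not pass the test (limma adjusted p = 0.090), but was called higher in the knockout with the covariate (1.87, adjusted p = 0.0058), with only the compared groups in the fit (0.016), without scaling (0.046) and without 12-43 replicate 1 or 2 (0.012 each). SC1 was called higher with the covariate (1.43, adjusted p = 0.0066) and Hyd1 lower without E6 replicate 2 (-0.86, adjusted p = 0.017). Of the fruiting-body regulators 4 were higher and 1 lower (camera adjusted p = 0.21, and 0.60 with the covariate). This list passed fry in the upward direction (fry adjusted p = 0.033). Fst3 differed by 1.03 (SE 0.12), WC1 by 0.89 (SE 0.12) and WC2 by -0.63 (SE 0.11), and by 0.76, 0.90 and -0.84 with the covariate. The calls on Fst4 (0.45, SE 0.093) and hom1 (0.40, SE 0.14) were lost with the covariate (adjusted p = 0.12 and 0.72) and without knockout replicate 1 (0.051 and 0.23), and that on hom1 also without knockout replicate 2 (0.055), without E6 replicate 1 (0.058) or 2 (0.20) and with upper-quartile scaling (0.082). Bri1 (0.28, SE 0.11) was called higher with voom (0.037), with unscaled RPKM (0.033) and without 12-43 replicate 1 (0.049), 12-43 replicate 2 (0.045) or E6 replicate 2 (0.047), and Gat1 (-0.091, SE 0.15) was called lower without E6 replicate 1 (-0.32, adjusted p = 0.045).

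Among models without a symbol, model 1163885 (359 ± 3.78 against 0.778 ± 0.270 RPKM; SD, n = 2 each) and model 1260454 (1114 and 1048 reads against 0 and 5) were highest in the knockout relative to E6, and model 1174659 (3.85 ± 0.624 against 854 ± 253 RPKM; SD, n = 2 each) and model 1190086 were lowest. The fitted log2 change of model 1260454 was 7.64, and it was 6.91 without E6 replicate 1 and 8.39 without E6 replicate 2. With the covariate the log2 changes of models 1163885 and 1260454 were 8.47 and 7.35, the log2 change of model 1174659 went from -7.69 to -8.43 and that of model 1190086 from -9.54 to -8.89. Limma called 7832 models, 3922 higher and 3910 lower in the knockout, of which 1598 and 1578 changed by at least 2-fold. This balance was 4333 higher and 3424 lower with unscaled RPKM and 3612 higher and 4264 lower with upper-quartile scaling. Each group lay wholly on its own side of the library split, so no library of either could stand in for the other within a side. In the fit with the library group as a covariate, where 12-43 links the sides, 4771 models were called and 2923 by at least 2-fold.

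Genes that changed the same way in the knockout against both wild types are those where the mutant stood apart from 2 strain backgrounds. Model 1124671 was at 3147 ± 259 RPKM in the knockout, 42.9 ± 39.9 RPKM in 12-43 and 24.0 ± 2.77 RPKM in E6 (SD, n = 2 each), and model 1205547 at 968 ± 135, 14.2 ± 15.9 and 5.95 ± 2.57 RPKM in the same order (SD, n = 2 each). Model 1083807 was lower, at 3.15 ± 1.41 RPKM against 325 ± 171 in 12-43 and 177 ± 21.5 in E6 (SD, n = 2 each), as was model 1100973, which had no read in the knockout and 202 and 219 reads in E6, at least 91.2-fold lower than in E6. The fitted log2 changes of model 1100973 against 12-43 and E6 went from -6.93 and -6.56 to -6.18 and -5.06 with the covariate. In the fit with the covariate the log2 changes against 12-43 and E6 went from 6.58 and 6.91 to 7.74 and 9.24 for model 1124671, from 6.66 and 7.19 to 8.14 and 10.16 for model 1205547, and from -6.42 and -5.74 to -5.81 and -4.53 for model 1083807. Against 12-43 they were 5.42 and 7.73 for model 1124671, 5.17 and 8.14 for model 1205547, and -7.02 and -5.82 for model 1083807 without 12-43 replicate 1 and 2. Of the genes with symbols, ura1, bap3-3, bbr2, brl1 and all bbp2 genes except bbp2-6 were higher, and SC3, HYD2, Hyd5, WC2 and CFS2 were lower, against each wild type. The calls against E6 on Hyd5 and CFS2 were lost with the covariate (adjusted p = 0.21 and 0.11), and those against 12-43 on WC2, CFS2 and bbr2 were lost under the settings given above. For bbr2 and the bbp2 genes the labels alone give a difference from E6, so that comparison adds little about the knockout. In all 3907 models passed both tests in the same direction, 2011 higher and 1896 lower, and 1151 did so by at least 2-fold. Independent lists of these sizes would share 1105 and 1033 models, but these lists share the knockout libraries. Simulated unchanged groups with the same shared knockout libraries gave a mean of 0.1 models over 20 draws. No model changes in them, so that number was nearly fixed in advance. Neither number is the overlap expected of 3 strains that differ, and 851 models passed both tests in opposite directions. Across genes the 2 sets of log2 changes correlated at 0.44, no higher than the 0.50 in the simulation, so the correlation shows no agreement beyond sharing the knockout. The covariance was 0.592 (0.0157 in the simulation), but it grows with the size of the changes. The shared knockout libraries were not split between the 2 comparisons, which would leave 1 library in each, so how much of the overlap comes from them stays open. The count was 2586 with the library group as a covariate, 2519 without knockout replicate 1 and 2487 without knockout replicate 2.

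The calls of the knockout and of E6 against 12-43 were also set side by side. In the same direction 3468 models were called in both, 1910 higher and 1558 lower, and 1007 were called in opposite directions. The 3468 are models where 12-43 stood apart from both other groups. Independent lists would share 1090 and 934, but these lists share the 12-43 libraries. The simulation of unchanged groups gave 0, which was nearly fixed in advance because no model changes in it. SC4, Hyd9, SC1, HYD2, Hyd1, brl3 and EGC1 were lower and Lcc1, ura1 and bbp2-6 higher in both the knockout and E6 than in 12-43. The calls on HYD2, Hyd1 and ura1 in E6, and on Lcc1 and bbp2-6 in the knockout, were lost under settings given above. The log2 changes of the 2 comparisons correlated at 0.48, no higher than the 0.50 in the simulation, so the correlation shows no agreement beyond sharing 12-43. Their covariance was 0.665 against 0.0155 in the simulation, but it grows with the size of the changes. The 12-43 libraries are common to these comparisons and were not split between them, so how much of the overlap comes from them stays open.

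Some models had reads in every library of a group and none in another. With at least 20 reads in each library of the first group, 30 models were read in the knockout and not in 12-43, and 6 in 12-43 and not in the knockout. Between the wild types, 70 models were read in E6 and not in 12-43, and 31 in 12-43 and not in E6. Between the knockout and E6 the counts were 27 read in the knockout alone of these groups and 36 in E6. The sum over these 6 ordered pairs of groups was 200, in which a model can count more than once, and it covered 128 distinct models. With at least 50 reads the sum was 106 (72 models), and with up to 2 reads allowed in each library of the second group it was 452 (262 models).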

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

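The quality reports list overrepresented sequences in the raw reads, which are outside the gene values compared above. In 12-43 replicate 2 an adapter sequence made up 17820 reads (0.1005% of the raw reads). In E6 replicate 1 an adapter sequence made up 20138 reads (0.101%), and a sequence for which the report names no source made up 20213 reads (0.101%). The other 4 libraries listed none.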

How the results depend on the processing

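The pseudocounts of 0.1 and 2 RPKM, unscaled RPKM and the library group as a covariate were chosen after the data had been examined. The counts of called models in the knockout and in E6 against 12-43 stayed within 1.5 times under all 18 alternatives, from 4826 to 7101 and from 6083 to 7552. The knockout against E6 ranged from 5881 to 8242, except for 4771 with the library group as a covariate, where the call rests on differences of differences through 12-43. Models changed the same way against both wild types numbered 2586 with that covariate and ranged from 2487 to 4014 when a library was left out. With a library left out its group has 1 library, which is assumed to vary like the others, and the read filter then needs 1 library. The sum over 6 ordered pairs of groups of models with reads in a group and none in another, in which a model can count more than once, was 106 with at least 50 reads and 452 with up to 2 reads allowed. The last 2 moves follow from the read thresholds. Of the 124 values of named genes, each fitted under these alternatives where its model was tested, none changed direction while called in either fit. With the covariate 113 kept their side of the threshold, 3 gained a call and 8 lost it.

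For the lists past camera, the cause of each change was not tested. In each comparison 0 lists passed with an estimated correlation. The other settings that lost a list are given with it above. For the knockout against 12-43, where 2 passed, 0 passed with a mean of at least 50 reads. For E6 against 12-43, where 2 passed, 1 passed with median-ratio scaling, 1 with a mean of at least 50 reads and 1 in each fit that left out a library (lowest 1, highest 1). For the knockout against E6, where 1 passed, 2 passed with fry. For E6 against 12-43 3 passed with fry. The list gained with fry was the fruiting-body regulators in both of these comparisons. With a mean of at least 50 reads the hydrophobins had too few members for a test.

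With the replicate number as a block 6577, 7214 and 7640 models were called in the knockout against 12-43, E6 against 12-43 and the knockout against E6, and 3755 the same way against both wild types. With that block the call on WC2 was lost in the knockout against 12-43 (adjusted p = 0.057) and in E6 against 12-43 (0.072), as was that on brl4 in the knockout against E6 (0.056), while SC6 was called higher in E6 than in 12-43 (0.037) and bbp2-6 lower in the knockout than in E6 (0.021). Deviations of same-numbered libraries correlated at 0.0029, 0.025 and -0.0011, which gives no sign that the numbers pair the samples. The 12-43 libraries lay on different sides of the library split and those of the other groups did not, so a weak pairing could be hidden.

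Tests with edgeR and DESeq2 were not run, since the files hold RPKM, and the dynein heavy chain genes gave no value under any setting. Depth limits genes with few reads: of the 9 tested hydrophobins Hyd1 had 8 to 34 reads per library. Hyd9 had 2 reads in each E6 library, HYD2 had 4 and 12 in the knockout, and Hyd4 had 5 and 14 in E6. Fitted changes of genes with low RPKM in a group moved with the pseudocount (in E6 against 12-43 bbp2-2, with 1 read in E6, from -5.74 at 0.1 to -2.67 at 2, and Lcc1, with 16 reads in 12-43, from 3.63 to 1.79). HYD2, Hyd9, bbr2, the bbp2 genes and most of the named models without a symbol also moved by over 1.5-fold with a pseudocount.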

Other observations

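The tests of depth over all models and of the batch from single libraries were chosen after the result was seen and the library group was defined after the data had been examined, while the other tests of the 3 patterns had their predictions written before their results were seen. Several values stood outside the comparisons. The tested models nearest to ura1, 3 of them within 10 genes in the reference order, differed between the knockout and 12-43 by 0.83 (model 71813, SE 0.14, limma adjusted p = 0.0018), 0.091 (model 49783, SE 0.14) and 0.11 (model 12631, SE 0.085) on the log2 scale, against 4.48 for ura1. Among the 794 longest tested models, model 65089 (10350 nt) was lower against both wild types, with log2 changes of -2.86 against 12-43 and -2.25 against E6 (SE 0.14 each) and 604 and 645 reads left in the knockout, as were model 1189910 (3723 nt), with -2.11 and -2.34 (SE 0.13 each), and model 1162637 (3738 nt), with -1.63 and -1.70 (SE 0.17 each). Only models 1325976 (483 nt) and 1100973 (432 nt) had at least 50 reads in each wild-type library and at most 5 in each knockout library. These genes were chosen after their values had been seen.

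The most abundant transcript varied between replicates. Model 1193825 took 1.29% and 4.07% of N in 12-43, 1.49% and 1.53% in the knockout and 4.84% and 2.36% in E6. Model 1057308 took 0.446% and 1.26%, 0.434% and 0.485%, and 1.25% and 0.612% in the same order. Neither passed the test in any comparison. The higher shares were all in libraries whose quality reports do not list GAAGA.

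The first pattern is the number of models that differ between the knockout and 12-43 by at least 2-fold, 2778. With the library group as a covariate 2785 models were called, but there 12-43 is a single library and the other groups supply the spread. A difference between library batches as the whole cause is argued against by folds of single libraries, without p-values: the 12-43 libraries, which lie in different library groups, differed by 2-fold or more in 234 of the tested models, and the knockout libraries differed from the 12-43 library of their own group in 2873 and 2840. Under 3 other scalings 2776 to 2791 were called, so the choice among these scalings hardly moved the number. All scaling factors lay between 0.933 and 1.06, too close to 1 to move it much. The result therefore does not test a larger shift that all of these scalings would miss. Neighbours could be judged only for the 2989 tested models placed in the reference order, and members of a pair lay up to 3 genes apart. Of 1501 such pairs, 116 had both members called at 2-fold or more. Shuffled orders gave a median of 77, with 95% of shuffles from 62 to 93 (one-sided permutation p = 1e-04, the smallest they can give). An excess of this kind is what blocks of differing genome background would give. E6 against 12-43 gave 138 pairs against 99, and the knockout against E6 gave 140 against 116 (one-sided permutation p = 0.0063). Neighbouring genes regulated together would give the same excess, so it remains open how far the mutant's background may differ from 12-43. The loss of dhc2 itself stays open as well, as the labels do not name the strain in which the gene was deleted.

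The second pattern is the set of 30 models with at least 20 reads in each knockout library and none in 12-43. After thinning every library to the total of the shallowest (8709341 reads) 30 of the 30 kept at least 10 reads in each knockout library, but the choice of these models nearly fixed that outcome, so it decides nothing. Lower depth of 12-43 as the cause is argued against by all 11302 models with at least 20 reads in each knockout library: given those reads and the denominators N, 3.31e-10 models would be expected to have no read in 12-43 if only depth differed, against the 30 seen. Of these models 24 had at least 20 reads in each E6 library and 0 lacked reads in E6. Genes present in the knockout and E6 but missing or diverged in 12-43 may account for this, as may genes silent in 12-43. With 5 of the 30 matched to the reference and no strain genomes used here, these were not tested against each other.

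The third pattern is the higher level of the 8 tested pheromone genes in the knockout, with a median log2 change of 2.07 against 12-43. A bias common to short genes is argued against by the median of -0.12 over the 585 other tested models of up to 300 nt. The pheromone median lay at percentile 94.4 of those models, so some single short models rose as much. A library batch is argued against by the median of 2.15 with the library group as a covariate. In that fit the knockout is set against 12-43 replicate 1 alone. Reads shared between near-identical pheromone genes, and a different mating state of the mycelia, which the labels describe in conflicting terms, may each play a part and were not tested. A link to the missing dynein gene is a hypothesis that these libraries do not separate from strain background.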
